A study of Homo sapiens with 282 samples.

How the data were processed

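The series holds expression profiles of OCI-Ly3 cells grown in 96-well plates and exposed to 14 compounds, to DMSO or to medium alone for 6, 12 or 24 h. RNA was hybridised to Affymetrix HT HG-U219 arrays. Values are log2 intensities made by the authors with RMA (background correction, quantile normalization and summary per probe set), per series labels and processing notes. The RMA version was not given. Labels gave compound, concentration, time and replicate number for each of 282 arrays. Array quality was judged from the upper quartile of log2 values, bioB hybridisation control and 3' to 5' differences of GAPDH and ACTB probe sets. The median standard error of a comparison of 3 treated with 8 DMSO arrays was 0.0988 at 6 h, 0.299 at 12 h and 0.276 at 24 h. Detection calls were not used, so genes near background stayed in.

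The value table has 49386 probe sets, of which 93 are controls. The platform annotation lists 46586, and 45259 of these carry 1 gene symbol; 1327 with several symbols or identifiers and 2713 not listed were left out of the gene tests. Symbols were brought up to date through the gene identifier for 45178 probe sets, and 0 of them changed. For 11823 genes with more than 1 probe set, the one with the highest mean over all arrays stood for the gene. This gave 18239 genes.

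The groups, the comparisons, the 30 gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Each time was fitted with limma 3.58.1 in R 4.3.3, as a mean per group over all 94 arrays of that time, with eBayes and a trend in the prior variance. Contrasts were each compound and concentration against DMSO, the higher against the lower concentration for 13 compounds, medium against DMSO, and doxorubicin against aclacinomycin A. The change from 6 to 24 h was a contrast of 2 differences in a fit of all 282 arrays. P-values were adjusted by Benjamini and Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. The higher concentration at 24 h is the main comparison; 6 h results were counted among the leading ones after the quality of the later arrays was seen.

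Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 420 tests at 24 h (30 lists and 14 compounds), and again with the correlation estimated from the data and with fry. List p-values at the preset correlation assume nearly independent genes, so those with an estimated correlation stand beside them. Lists cover p53 targets, mitosis, replication, repair, histones, stress responses, metabolism, signalling, cytoskeleton and B cell identity, and 5 hold markers of other cell types; 4 lists were fixed for each compound. Members absent from the array were left out. Similarity of responses was the Pearson correlation and the covariance of log2 fold changes across genes, for 4 classes of pairs fixed beforehand. It was compared with unchanged groups simulated 20 times against the shared DMSO arrays, with the spread pooled over all groups and, chosen after that was seen, with the spread among DMSO arrays.

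The fixed alternatives were quantile normalization again, leaving out the 40% of genes with the lowest mean, the mean of all probe sets of a gene, only the arrays of the groups compared, the replicate number as a block, and leaving out each replicate in turn. Replicate numbers were left out of all drug groups at once, methotrexate arrays and DMSO replicates 1 at a time. Added after seeing the data were leaving out low-signal arrays (upper quartile under 8 or ACTB difference over 2), the bioB level as a covariate, and array weights estimated gene by gene, since the REML weights did not converge at 12 and 24 h. Arrays were also regrouped at random, up to 100 splits per comparison with the real one among them, and all 45 or 10 where no more exist. A count was called the same if within 1.5 times the main count.

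The fit was tested on simulated data, not the uneven arrays, with 200 genes of the doxorubicin comparison changed. At 6, 12 and 24 h, a change of 0.5 was found for 91.04, 0 and 13.43% of genes, a change of 1 for 100, 41.79 and 52.24%, and a change of 2 for 100, 96.97 and 95.45%, with 13, 6 and 10 of 18005 unchanged genes called. A list shift of 0.5 in the p53 targets was found at each time, with adjusted p = 3.47e-104, 3.4e-13 and 1.1e-10, and 0 of 29 other lists was called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 drew the figures. Arrays were not removed from the main results, and genes that mark the sex of the donor are not described.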

Results

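Gene expression was measured in OCI-Ly3, a human cell line from a diffuse large B cell lymphoma, after exposure to 14 compounds for 6, 12 or 24 h. The series was built as a resource for predicting the response to a pair of compounds from each alone. Each of 282 microarrays, 94 per time, belonged to 1 of 87 groups. DMSO, the vehicle, had 8 arrays per time, untreated medium 2, methotrexate 6 at its only concentration of 100 uM, and every other compound 3 at each of 2 labelled concentrations. The 6 methotrexate arrays of a time carry only the replicate numbers 1, 2 and 3. If they are repeats of 3 samples, n = 6 is too high and the standard errors are too small. The 2 etoposide concentrations, 0.811 and 0.812 uM, differed so little that they served as a repeat. Changes below are log2 fold changes ± standard error against the 8 DMSO arrays of the same time, from limma with Benjamini-Hochberg adjustment over 18239 genes, with 3 treated arrays unless another n is given. Replicates left out in turn include those of DMSO. Background was not measured. GDF15 in DMSO and under aclacinomycin A lay below the median of every array (at least 5.59 at 24 h), so its changes may be understated. For each gene named among the largest rises or falls of a compound at 24 h, all treated arrays lay on one side of all 8 DMSO arrays. The labels do not say that replicates came from separate cultures, so their spread may be technical. P-values use 1 spread per gene, pooled over all groups of a time.

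The arrays of 12 and 24 h were less even than those of 6 h. The upper quartile of log2 values lay between 8.15 and 8.35 on all 94 arrays at 6 h, but went down to 6.91 at 12 h and to 6.92 at 24 h. Low arrays carried more of the bioB hybridisation control, a bacterial transcript added in fixed amount. Across the 94 arrays of a time, Pearson's r between the quartile and bioB was -0.68 at 6 h, -0.86 at 12 h and -0.85 at 24 h, and Spearman's rho was -0.59, -0.97 and -0.80. Each relation had a permutation p and adjusted p of 1e-05, the smallest that 100000 resamples can give. Without the 2 arrays farthest from the median upper quartile, r was -0.57, -0.87 and -0.82. Arrays with an upper quartile under 8, or an ACTB 3' to 5' probe set difference over 2, numbered 0 of 94 at 6 h, 31 at 12 h and 17 at 24 h, and are called low-signal arrays below. These limits were set after array quality was seen. Without them, a group left with 1 array takes its spread from others. Pooled standard errors at 12 and 24 h are likely too large for even groups and too small for those with low-signal arrays. Counts there may partly track array quality.

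**Figure D1:**
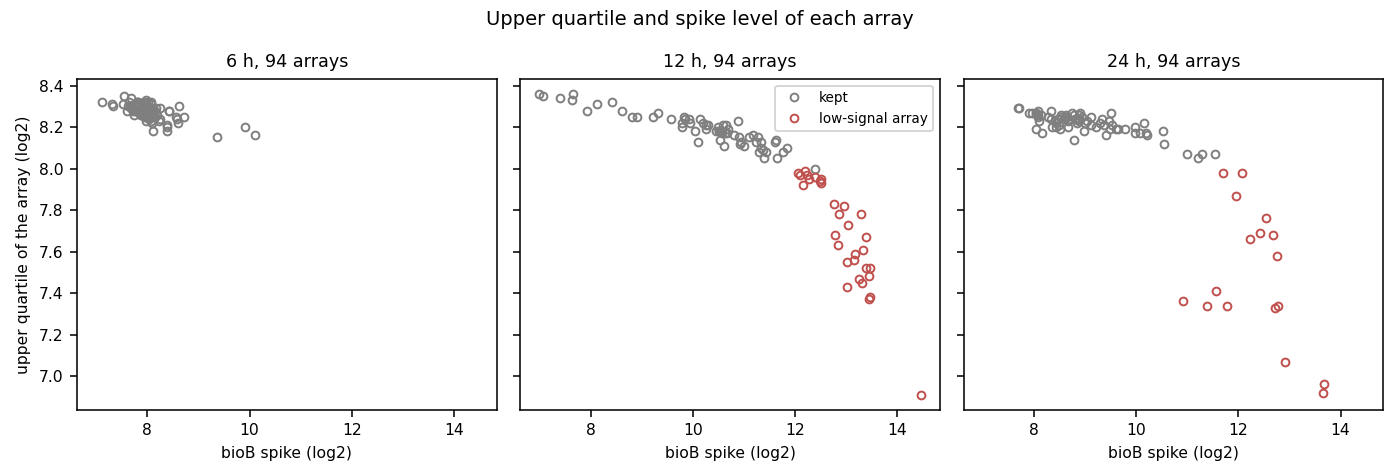
Upper quartile of the log2 values of each array (vertical axis) against its log2 bioB level (horizontal axis), in a panel for each of 6, 12 and 24 h with 94 arrays each; red circles mark the low-signal arrays. At 6 h all arrays lie between 8.15 and 8.35, while at 12 and 24 h some go down to 6.91 and 6.92.

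At the higher concentration and 24 h, the number of genes that passed an adjusted p of 0.05 ran from 0 for aclacinomycin A to 4711 for mitomycin C. Camptothecin changed 1497 genes, doxorubicin 1107, trichostatin A 912, methotrexate 865, rapamycin 455, etoposide 265 and monastrol 220. Blebbistatin changed 9, vincristine 8 and geldanamycin 4. Without the low-signal arrays the median standard error of a comparison of 3 arrays went from 0.276 to 0.12, and counts from 5442 for mitomycin C to 6514 for doxorubicin were reached by 7 compounds, the others being camptothecin, methotrexate, monastrol, cycloheximide and trichostatin A. At 6 h, where no array was low, counts ran from 141 for aclacinomycin A to 9126 for H-7.

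**Figure D2:**
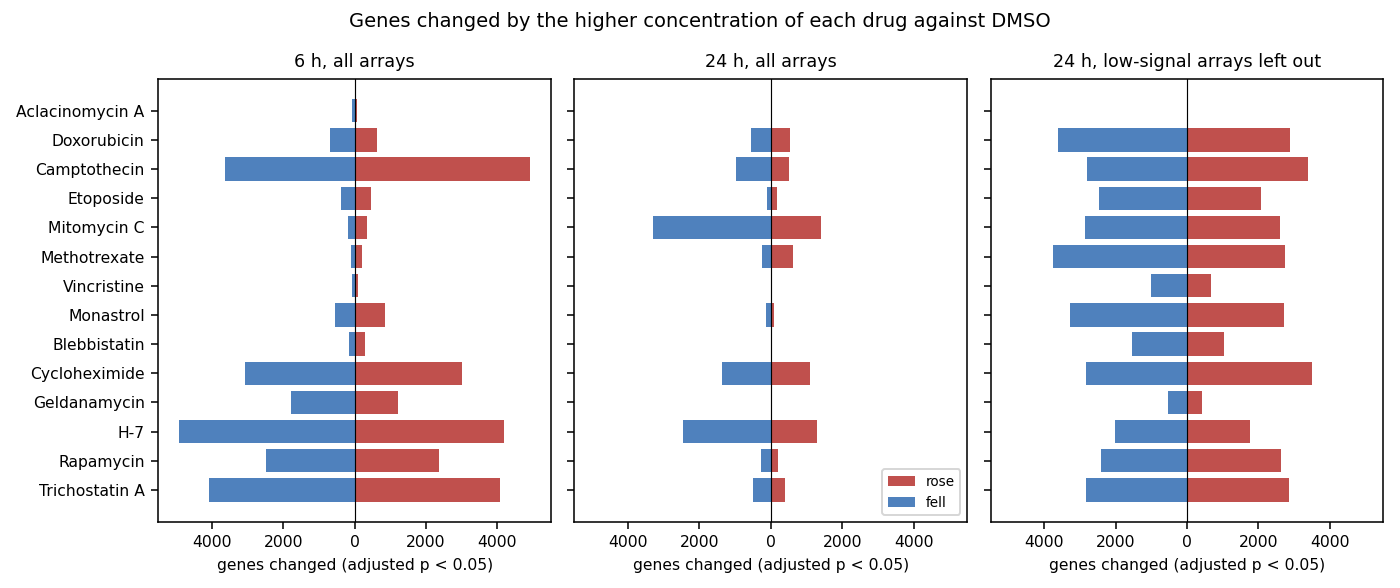
Genes that rose (right of 0) or fell (left of 0) against DMSO at the higher concentration of each of 14 compounds at 6 h, 24 h and 24 h without the low-signal arrays (adjusted p under 0.05). At 24 h they run from 0 for aclacinomycin A to 4711 for mitomycin C.

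Doxorubicin, an anthracycline that traps topoisomerase II on DNA, was compared with DMSO to follow the response to DNA damage. At 0.101 uM and 24 h, 547 genes rose and 560 fell. LCE1C, a late cornified envelope gene, rose by 5.36 ± 0.26, and GDF15, a stress cytokine and p53 target, by 5.33 ± 0.40, from a level of 4.07 ± 0.542 (SD, n = 8) to 9.39 ± 0.031 (SD, n = 3). The sulfatase gene SULF2 rose by 4.46 ± 0.37 and the adhesion gene NECTIN4 by 3.79 ± 0.31. Cyclin E2 (CCNE2) changed by -2.80 ± 0.34 and the mitotic kinesin KIF14 by -2.54 ± 0.23. Of 34 measured p53 targets, 27 rose and 0 fell (32 and 0 adjusted over the list alone), among them TP53I3 by 3.35 ± 0.27 and SESN1 by 2.64 ± 0.36. The median shift of the list was 1.48 (camera, adjusted p = 4.11e-61, and 0.000154 with an estimated correlation). Of 32 mitosis genes, 13 fell and 0 rose (20 and 0 over the list alone), among them PLK1 at -2.13 ± 0.48 (adjusted p = 0.0013) and CCNA2 at -2.06 ± 0.44. Their median was -0.84, with adjusted p = 1.18e-17, and adjusted p = 0.214 with an estimated correlation. Of 33 DNA replication genes, 20 fell and 0 rose (23 and 1 over the list alone) with a median of -0.98, adjusted p = 1.13e-19, and adjusted p = 0.129 with an estimated correlation. Among 19 histone genes 5 rose and 2 fell (7 and 2 over the list alone), with H2BC5 up by 1.30 ± 0.28, a median of 0.44 and adjusted p = 0.000834, and adjusted p = 0.245 with an estimated correlation. Leaving out the low-signal arrays, 2893 genes rose and 3621 fell, and the mitosis and replication medians were -0.88 and -1.01, with adjusted p = 2.96e-07 and 6.94e-10 under an estimated correlation. Without replicate 1 of the drug groups, 630 genes passed.

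Camptothecin, which traps topoisomerase I on DNA, raised 510 genes and lowered 987 at 0.31 uM and 24 h. The deepest falls were in RABGAP1L at -4.77 ± 0.31, AOPEP at -4.38 ± 0.33, GPHN at -3.91 ± 0.25, GRIN2A at -3.87 ± 0.38 and VPS13B at -3.87 ± 0.34. The largest rises were in LCE1C at 4.03 ± 0.26, NECTIN4 at 3.24 ± 0.31, the interferon-induced gene IFIT2 at 3.03 ± 0.27 and the chemokine gene CCL22 at 2.97 ± 0.35. Of 32 mitosis genes 29 fell and 0 rose, the same counts adjusted over the list alone, with a median of -1.81 (camera, adjusted p = 9.46e-41, and 0.0201 with an estimated correlation). CENPF changed by -3.08 ± 0.44 and ASPM by -2.94 ± 0.41. Of 34 p53 targets 17 rose and 0 fell (21 and 0 over the list alone), with a median of 0.99, adjusted p = 2.71e-20, and adjusted p = 0.0623 with an estimated correlation. Of 33 DNA replication genes 16 fell and 0 rose (25 and 0 over the list alone), at a median of -0.92, adjusted p = 4.51e-16, and adjusted p = 0.196 with an estimated correlation. DNA repair genes had 6 of 19 down and 0 up (12 and 0 over the list alone), among them BRCA1 at -1.48 ± 0.26, at a median of -0.84, adjusted p = 1.04e-08, and adjusted p = 0.214 with an estimated correlation. Interferon response genes had 11 of 33 up and 1 down (14 and 1 over the list alone), at a median of 0.42, with adjusted p = 7.88e-09, and 7.67e-06 with an estimated correlation. The count was 3395 up and 2811 down without the low-signal arrays, and without replicate 1 of the drug groups 939 genes passed.

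Etoposide, another topoisomerase II poison, raised 169 genes and lowered 96 at 0.812 uM and 24 h. LCE1C rose by 4.41 ± 0.26, SULF2 by 3.69 ± 0.37, GDF15 by 3.24 ± 0.40 and BLNK, an adaptor of B cell receptor signalling, by 2.84 ± 0.23. The mitotic genes PLK1, CDC20 and CCNB1 changed by -2.14 ± 0.48, -1.76 ± 0.33 and -1.70 ± 0.29. Of 34 p53 targets 19 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 1.15 (camera, adjusted p = 7.43e-70, and 5.38e-05 with an estimated correlation). Of 32 mitosis genes 14 fell and 0 rose (27 and 0 over the list alone), with a median of -1.08, adjusted p = 5.85e-43, and 0.0154 with an estimated correlation. DNA replication genes had 4 of 33 down and 0 up (17 and 0 over the list alone) at a median of -0.65, adjusted p = 2.94e-15, and adjusted p = 0.218 with an estimated correlation. DNA repair genes had 0 of 19 called at a median of -0.32, adjusted p = 0.0122, and adjusted p = 0.769 with an estimated correlation. The fit without the low-signal arrays had 2082 up and 2473 down. Without replicate 1 of the drug groups 124 passed. The repeat at 0.811 uM changed 677 genes, and 0 genes differed between the 2 concentrations by limma, with 1077 at an unadjusted p under 0.05 and 37 without the low-signal arrays. At 6 h 39 differed, 3 higher and 36 lower at 0.812 uM.

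Mitomycin C, which crosslinks DNA, raised 1418 genes and lowered 3293 at 2.56 uM and 24 h, but replicate 2 was a low-signal array and much of this count came with it. LCE1C rose by 4.96 ± 0.26, NECTIN4 by 3.86 ± 0.31, BLNK by 3.77 ± 0.23 and GDF15 by 3.63 ± 0.40. WWOX, a gene spanning a common fragile site, changed by -2.92 ± 0.20, and the complement receptor gene CR2 by -2.59 ± 0.26. Those 6 genes stood, without the low-signal arrays, at 4.97, 4.30, 3.78, 4.84, -2.55 and -1.67, while FBXO11 went from -2.40 ± 0.55 to -0.86 and M6PR from -2.38 ± 0.49 to -0.64. Of 34 p53 targets 20 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 0.95, adjusted p = 1.78e-15 by camera, and adjusted p = 0.127 with an estimated correlation; the median was 1.57 without the low-signal arrays. The mitosis genes had 18 of 32 down and 0 up (20 and 0 over the list alone) at a median of -0.85, with adjusted p = 0.702 with an estimated correlation, and their median was -0.03 without the low-signal arrays. Of 33 DNA replication genes 13 fell and 0 rose (17 and 0 over the list alone) at a median of -0.81, with adjusted p = 0.769 with an estimated correlation, and a median of -0.22 without those arrays. DNA repair genes, with 2 of 19 down and 0 up (0 and 0 over the list alone), had a median of -0.29 (adjusted p = 0.465), against 0.16 without those arrays (adjusted p = 0.00443). Without replicate 2, 552 genes passed, without replicate 1 7446 and without replicate 3 9722. The fit without the low-signal arrays had 2597 up and 2845 down, and 2234 genes were called both with and without them.

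Methotrexate, an inhibitor of dihydrofolate reductase, raised 624 genes and lowered 241 at 100 uM and 24 h (n = 6). NECTIN4 rose by 3.67 ± 0.25, the early response gene EGR4 by 3.31 ± 0.20, SULF2 by 3.23 ± 0.29 and PLAU, which encodes urokinase, by 3.12 ± 0.37. NDP changed by -1.41 ± 0.17 and TSPOAP1 by -1.39 ± 0.22. Of 34 p53 targets 24 rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 1.33 (camera, adjusted p = 8.09e-64, and 0.000116 with an estimated correlation). Immediate early genes had 14 of 30 up and 0 down (20 and 0 over the list alone), with a median of 0.74 and FOSL1 up by 2.26 ± 0.23 (adjusted p = 9.74e-30, and 0.00509 with an estimated correlation). Of 32 mitosis genes 5 rose and 0 fell (11 and 0 over the list alone), with a median of 0.38, adjusted p = 9.39e-09, and adjusted p = 0.553 with an estimated correlation. DNA replication genes had 4 of 33 up and 0 down (5 and 0 over the list alone), with a median of 0.22, adjusted p = 0.000659, and adjusted p = 0.769 with an estimated correlation. Of 28 folate and nucleotide synthesis genes, the thymidylate synthase gene TYMS rose by 0.57 ± 0.12 and the purine synthesis gene PFAS changed by -0.73 ± 0.14, with 1 up and 1 down in all (1 and 2 over the list alone) and a median of -0.21 (adjusted p = 0.345). Leaving out the low-signal arrays, 2744 genes rose and 3754 fell.

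Vincristine and monastrol both act on the mitotic spindle, the first by blocking tubulin assembly and the second by inhibiting the kinesin KIF11. Vincristine at 0.01 uM raised 4 genes and lowered 4 at 24 h. The histone genes H2BC5 and H2BC15 rose by 1.61 ± 0.28 and 1.61 ± 0.27, the S phase regulators E2F8 and E2F1 changed by -1.39 ± 0.26 and -1.04 ± 0.23, and the tubulin gene TUBB4B by -0.30 ± 0.06 (adjusted p = 0.046). The 18 tubulin genes had 0 up and 1 down (0 and 2 adjusted over the list alone) and a median of -0.09, with adjusted p = 0.000222 by camera, and adjusted p = 0.174 with an estimated correlation. No p53 target passed over all genes (12 rose and 0 fell over the list alone), yet the list's median of 0.54 stood above the other genes (adjusted p = 5.48e-35, and 0.00624 with an estimated correlation). The mitosis genes had a median of 0.08 (adjusted p = 0.591) and the immediate early genes one of 0.21, with adjusted p = 1.26e-10, and adjusted p = 0.188 with an estimated correlation. Monastrol at 100 uM raised 88 genes and lowered 132. H2AC6 rose by 2.03 ± 0.29 and H2BC5 by 1.88 ± 0.28, and PLCXD1 changed by -2.16 ± 0.28, with CCNE2 also among the genes that fell. DNA replication genes had 7 of 33 down and 0 up (17 and 0 over the list alone), at a median of -0.75, adjusted p = 2.07e-18, and adjusted p = 0.154 with an estimated correlation. The mitosis, p53 and tubulin medians of monastrol were 0.07, 0.08 and -0.03 (adjusted p = 0.336, 0.198 and 0.795), and aryl hydrocarbon receptor targets stood at -0.11 (adjusted p = 0.439). Without the low-signal arrays vincristine raised 664 genes and lowered 1019, and monastrol 2719 and 3267. Leaving out 1 replicate in turn, vincristine gave 0 to 9 and monastrol 9 to 909.

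Blebbistatin, an inhibitor of myosin II, raised 6 genes and lowered 3 at 100 uM and 24 h. IFIT2 rose by 2.18 ± 0.27, SULF2 by 1.68 ± 0.37 and TRIM22 by 1.38 ± 0.30, and the replication genes TICRR and MCM10 changed by -1.08 ± 0.22 and -0.80 ± 0.18. Of 34 p53 targets 1 rose (10 over the list alone, with 0 down), at a median of 0.57 (camera, adjusted p = 1.17e-33, and 0.00759 with an estimated correlation). DNA replication genes had 1 of 33 down (12 over the list alone, with 0 up), at a median of -0.60 (adjusted p = 6.80e-39, and 0.0131 with an estimated correlation). The interferon response genes had a median of 0.17 (adjusted p = 2.39e-13, and 2.42e-08 with an estimated correlation). Mitosis genes stood at -0.48, with adjusted p = 2.97e-19, and adjusted p = 0.186 with an estimated correlation. Actin and myosin cytoskeleton genes stood at 0.12, with adjusted p = 0.012, and adjusted p = 0.768 with an estimated correlation. Aryl hydrocarbon receptor targets stood at -0.22, with adjusted p = 0.0246, and adjusted p = 0.101 with an estimated correlation, and NRF2 and metal response genes at 0.02 (adjusted p = 0.85). The fit without the low-signal arrays had 1036 up and 1547 down. Leaving out 1 replicate in turn gave 1 to 8 genes.

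Cycloheximide, which blocks translation elongation, raised 1089 genes and lowered 1371 at 5 uM and 24 h. KLF2, a transcription factor of quiescent lymphocytes, rose by 3.04 ± 0.32, IFIT2 by 2.60 ± 0.27 and TSC22D3 by 2.31 ± 0.37. DHCR7, which catalyses the last step of cholesterol synthesis, changed by -3.32 ± 0.38 and the matrix gene POSTN by -3.13 ± 0.41. Cholesterol and fatty acid synthesis genes had 14 of 24 down and 0 up (17 and 0 adjusted over the list alone), at a median of -1.08, with adjusted p = 1.03e-13 by camera, and adjusted p = 0.186 with an estimated correlation. Tubulin genes had 10 of 18 down and 0 up (11 and 0 over the list alone), TUBB among them at -1.44 ± 0.19, at a median of -0.62 (adjusted p = 1.36e-11, and 0.00297 with an estimated correlation). Endoplasmic reticulum chaperone genes had 7 of 20 down and 0 up (11 and 0 over the list alone), at a median of -0.79, adjusted p = 1.28e-07, and adjusted p = 0.473 with an estimated correlation. Ribosomal protein genes had 5 of 47 down and 0 up (3 and 0 over the list alone), at a median of -0.07, adjusted p = 0.0206, and adjusted p = 0.868 with an estimated correlation. Ribosome biogenesis and MYC-linked genes had 3 of 31 down, with MYC at -1.19 ± 0.25, and a median of -0.23, adjusted p = 0.0252, and adjusted p = 0.846 with an estimated correlation; with bioB as a covariate the median was 0.27. Immediate early genes, with 3 up and 3 down of 30 and a median of -0.12, and NF-kappaB targets, with 2 up and 1 down of 28 and a median of -0.07, gave no call (adjusted p = 0.783 and 0.796). The early median was 0.39 with bioB as a covariate. Leaving out the low-signal arrays, with 1 cycloheximide array then left, 3518 genes rose and 2829 fell, and without replicate 1 of the drug groups 1354 passed.

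H-7, an inhibitor of protein kinases, raised 1308 genes and lowered 2462 at 20.2 uM and 24 h, a count that rested on replicate 3, a low-signal array. Immediate early genes had 16 of 30 down and 0 up (17 and 1 adjusted over the list alone), with IER2 at -2.39 ± 0.50, DUSP1 at -2.32 ± 0.64 and FOS at -1.91 ± 0.31 (-0.26, -0.78 and -1.19 without the low-signal arrays). The list's median was -0.93, with adjusted p = 1.40e-07 by camera, and adjusted p = 0.372 with an estimated correlation; without the low-signal arrays it was -0.38, with adjusted p = 9.19e-07 with an estimated correlation. RASGRP3, an activator of Ras, rose by 1.60 ± 0.38. Mitosis genes had 12 of 32 down and 0 up (15 and 0 over the list alone), at a median of -0.85, adjusted p = 2.72e-05, and adjusted p = 0.728 with an estimated correlation; without those arrays the median was -0.29, with adjusted p = 0.00349 with an estimated correlation. NF-kappaB targets had 2 up and 9 down of 28 (3 and 9 over the list alone) and a median of -0.37 (adjusted p = 0.122; 0.04 without those arrays), and apoptosis regulators 0 up and 6 down of 22 (1 and 6 over the list alone) and a median of -0.05 (adjusted p = 0.564; 0.05 without those arrays). Without replicate 3 of the drug groups 51 genes passed, without replicate 1 7480 and without replicate 2 6582. The fit without the low-signal arrays had 1775 up and 2022 down, and 1380 genes were called both with and without them.

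Geldanamycin, an inhibitor of the chaperone HSP90, raised 4 genes and lowered 0 at 0.032 uM and 24 h by limma, with 153 at an unadjusted p under 0.05. The genes were CTLA4 at 1.47 ± 0.26, PLAAT4 at 1.34 ± 0.28, the extracellular chaperone CLU at 1.29 ± 0.22 and GPR155 at 0.98 ± 0.20. Of 23 heat shock genes 0 passed, over all genes or over the list alone, and their median was 0.30, with adjusted p = 5.80e-14 by camera, and adjusted p = 0.101 with an estimated correlation. From the arrays of even signal, 14 of the 23 rose and 0 fell, with a median of 0.28 and adjusted p = 4.01e-10 with an estimated correlation. NF-kappaB targets stood at -0.12, adjusted p = 1.17e-05, and adjusted p = 0.408 with an estimated correlation, while B cell identity genes at -0.04 and apoptosis regulators at 0.03 gave no call (adjusted p = 0.555 and 0.34). The fit without the low-signal arrays had 429 up and 520 down. Leaving out 1 replicate in turn gave 0 to 4 genes.

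Rapamycin, an inhibitor of mTOR, raised 193 genes and lowered 262 at 22 uM and 24 h. The inducible heat shock gene HSPA6 rose by 4.18 ± 0.24, IFIT2 by 3.46 ± 0.27 and the cystine transporter gene SLC7A11 by 1.83 ± 0.24. HK2, the hexokinase that starts glycolysis, changed by -2.18 ± 0.33. Mitosis genes had 12 of 32 down and 0 up (29 and 0 adjusted over the list alone), at a median of -1.14 (camera, adjusted p = 6.07e-33, and 0.0465 with an estimated correlation). DNA replication genes had 11 of 33 down and 0 up (26 and 0 over the list alone), at a median of -0.93 (adjusted p = 5.67e-30, and 0.0422 with an estimated correlation). Interferon response genes had 8 of 33 up and 0 down (14 and 0 over the list alone), at a median of 0.47 (adjusted p = 7.19e-14, and 2.42e-08 with an estimated correlation). Ribosome biogenesis and MYC-linked genes had 5 of 31 down and 0 up (14 and 0 over the list alone), WDR12 among them at -1.22 ± 0.23, at a median of -0.71, adjusted p = 9.36e-18, and adjusted p = 0.188 with an estimated correlation. Glycolysis and hypoxia genes had 4 of 31 down and 0 up (6 and 0 over the list alone), at a median of -0.29, adjusted p = 1.08e-07, and adjusted p = 0.387 with an estimated correlation. Cholesterol and fatty acid synthesis genes had 1 of 24 down (1 over the list alone), ACAT2 at -0.91 ± 0.26, at a median of -0.35, adjusted p = 0.00363, and adjusted p = 0.78 with an estimated correlation. Ribosomal protein genes had 1 of 47 up (1 over the list alone), RPL38 at 0.49 ± 0.14, and a median of 0.08, adjusted p = 0.00298, and adjusted p = 0.826 with an estimated correlation. The count without the low-signal arrays was 2650 up and 2404 down.

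Trichostatin A, an inhibitor of histone deacetylases, raised 404 genes and lowered 508 at 0.143 uM and 24 h. SPRR2D, a cornified envelope gene, rose by 3.37 ± 0.29, the chemokine gene CCL22 by 3.37 ± 0.35, the steroid reductase gene AKR1C3 by 2.55 ± 0.41 and the cytokine gene IL6 by 2.51 ± 0.37. CA2, a carbonic anhydrase, changed by -2.43 ± 0.35 and the mitotic kinesin KIF20A by -2.39 ± 0.40. Mitosis genes had 24 of 32 down and 0 up (29 and 0 adjusted over the list alone), at a median of -1.41 (camera, adjusted p = 1.93e-33, and 0.0465 with an estimated correlation). Interferon response genes had 5 of 33 up and 0 down (14 and 1 over the list alone), at a median of 0.47 (adjusted p = 2.96e-06, and 0.000206 with an estimated correlation). NF-kappaB targets had 6 of 28 up and 1 down (7 and 1 over the list alone), the apoptosis inhibitor gene BCL2A1 being the member that fell, at -1.51 ± 0.36. Their median was 0.32, with adjusted p = 6.88e-05, and adjusted p = 0.473 with an estimated correlation. Histone genes (1 of 19 up, H2AC8 at 0.86 ± 0.21), B cell identity genes (VPREB3 up by 0.87 ± 0.26, CIITA at -1.08 ± 0.27) and apoptosis regulators (0 of 22) had medians of 0.10, 0.11 and -0.12 and no call (adjusted p = 0.26, 0.609 and 0.953). The count without the low-signal arrays was 2862 up and 2834 down. Without replicate 1 of the drug groups 197 genes passed, without replicate 2 1792 and without replicate 3 2631.

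**Figure D3:**
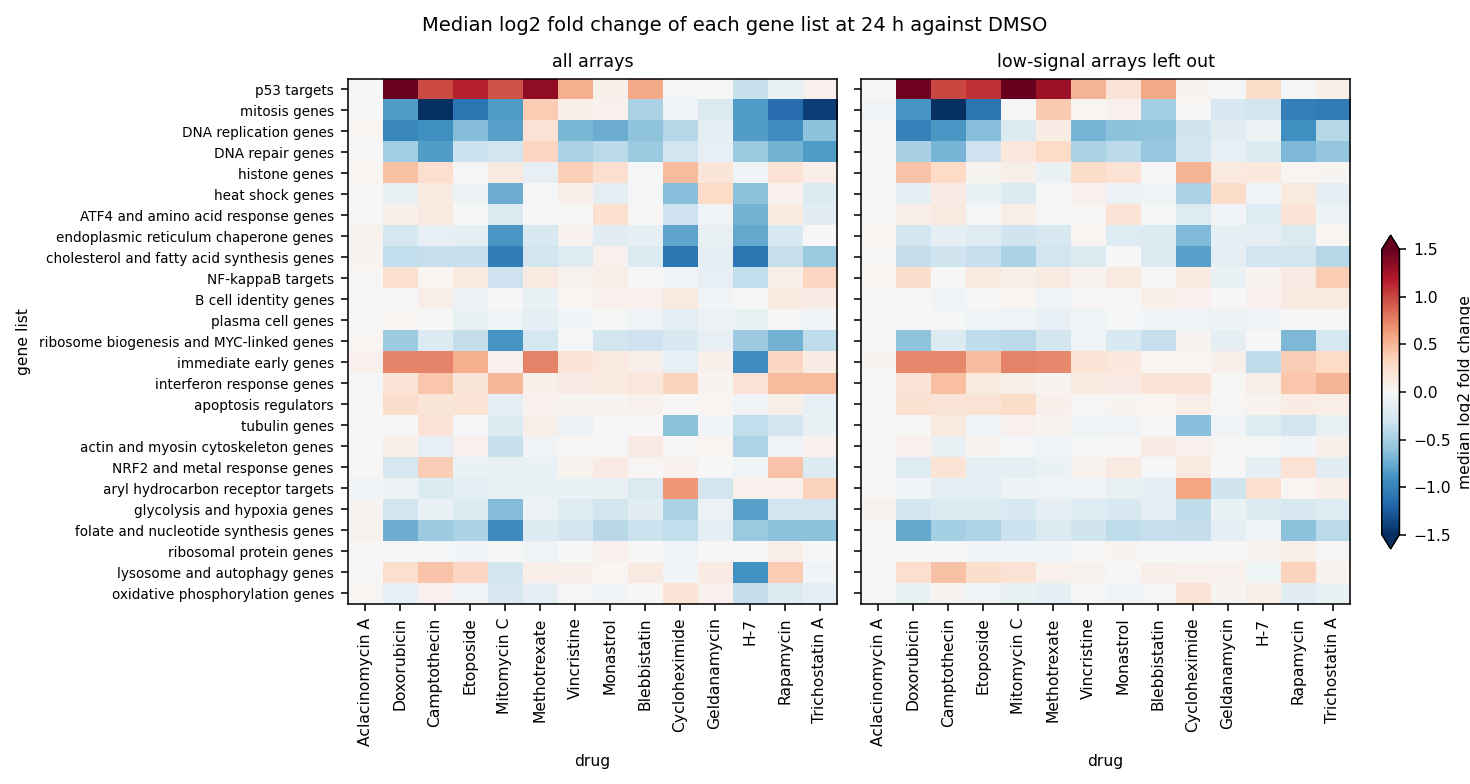
Median log2 fold change against DMSO at 24 h of each gene list (vertical axis) in each of 14 compounds at the higher concentration (horizontal axis), by colour, with all arrays and without the low-signal arrays. With all arrays the p53 targets reach 1.48 under doxorubicin, and the mitosis genes -1.81 under camptothecin.

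Doxorubicin and aclacinomycin A are both anthracyclines, at nearly the same concentration (0.101 and 0.105 uM), and were compared directly. At 24 h 319 genes were higher and 261 lower under doxorubicin. GDF15 differed by 5.69 ± 0.49, LCE1C by 5.34 ± 0.32 and SULF2 by 4.50 ± 0.44, and CCNE2 by -3.06 ± 0.41 and KIF14 by -2.51 ± 0.27 (SE, n = 3 and 3). At 6 h 441 were higher and 252 lower, led by SULF2 at 1.61 ± 0.12 and PLK1 at -1.48 ± 0.08, and at 12 h 56 and 54, led by LCE1C at 3.13 ± 0.36 and CENPE at -2.92 ± 0.48. At 12 h every array of both drugs at these concentrations was a low-signal array. Aclacinomycin A against DMSO changed 0 genes at 24 h by limma, with 7 at an unadjusted p under 0.05 where chance gives 912, and again 0 without the low-signal arrays, with 691. The median 95% interval of its fold changes then reached 0.24 to either side, and the largest estimate was 0.74 in size. Its own lists, p53 targets at 0.01, histone genes at 0.03, ribosome biogenesis and MYC-linked genes at 0.03 and immediate early genes at 0.07, had 0 members called; the last had adjusted p = 0.0279, and adjusted p = 0.811 with an estimated correlation. With 1 replicate of both drugs left out in turn, 251 to 523 genes differed between them at 24 h, 20 to 1285 at 12 h and 312 to 467 at 6 h. The fit without the low-signal arrays had 2532 higher and 3091 lower at 24 h.

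At 6 h all arrays were of even signal. The p53 targets rose as a list under 8 of 14 compounds at their higher concentrations, and under 7 of them with an estimated correlation. Under doxorubicin 29 of 34 rose and 0 fell (31 and 0 adjusted over the list alone), at a median of 0.77, under camptothecin 31 and 0 at a median of 1.13, under etoposide 28 and 0 at 0.70, under mitomycin C 24 and 0 at 0.39, and under H-7 27 and 5 at 0.50. Mitosis genes fell as a list under 9 compounds, 8 of them with an estimated correlation. Their medians were -1.07 under camptothecin, -0.84 under etoposide with 31 of 32 down, -0.64 under doxorubicin with 29 down and -0.59 under mitomycin C with 27 down, while under vincristine 11 rose and 0 fell at a median of 0.19 (camera, adjusted p = 2.79e-24, and 3.73e-07 with an estimated correlation). Under mitomycin C 26 of 33 DNA replication genes rose and 0 fell at a median of 0.28 (adjusted p = 2.60e-50, and 9.36e-18 with an estimated correlation). Under geldanamycin 22 of 23 heat shock genes rose and 0 fell at a median of 0.94 (adjusted p = 9.09e-102, and 5.42e-21 with an estimated correlation). Under rapamycin 27 of 30 ATF4 and amino acid response genes rose and 0 fell at a median of 0.88 (adjusted p = 6.61e-65, and 5.59e-20 with an estimated correlation). Under cycloheximide 22 of 30 immediate early genes rose and 0 fell at a median of 0.56, and 16 of 19 histone genes rose at 0.73 (with an estimated correlation, adjusted p = 4.12e-09 and 1.23e-07). Under monastrol 14 of 24 cholesterol and fatty acid synthesis genes rose and 0 fell at a median of 0.26 (adjusted p = 6.49e-12 with an estimated correlation). H-7 raised 4197 genes and lowered 4929, camptothecin 4917 and 3633, trichostatin A 4066 and 4094, cycloheximide 3018 and 3073, rapamycin 2367 and 2482, geldanamycin 1227 and 1779, monastrol 840 and 545, doxorubicin 621 and 682, etoposide 453 and 381, mitomycin C 343 and 199, blebbistatin 304 and 168, methotrexate 213 and 107, vincristine 97 and 76, and aclacinomycin A 63 and 78. Leaving out 1 replicate in turn moved 9 counts by over 1.5 times: geldanamycin gave 1913 to 2946, monastrol 572 to 1433, doxorubicin 712 to 1401, etoposide 453 to 844, mitomycin C 258 to 555, blebbistatin 130 to 716, methotrexate 6 to 1108, vincristine 17 to 627 and aclacinomycin A 0 to 432.

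The change between 6 and 24 h was tested as a difference of differences, with both counts without the low-signal arrays in brackets. Under trichostatin A 651 responses were higher and 1139 lower (3362 and 3236) at 24 h, with the chemokine gene CCL1 at 5.11 ± 0.36, IL6 at 4.23 ± 0.40 and CA2 at -3.69 ± 0.43. Under doxorubicin 122 were higher and 83 lower (1650 and 2059), led by GDF15 at 5.17 ± 0.46, LCE1C at 3.81 ± 0.34 and BLNK at 3.26 ± 0.29. Under camptothecin 88 were higher and 263 lower (2291 and 2053), with CCL22 at 2.59 ± 0.37 and WWOX at -3.05 ± 0.27. Under methotrexate 366 were higher and 91 lower (2052 and 2908), led by NECTIN4 at 3.85 ± 0.34 and EGR4 at 3.33 ± 0.26. Under cycloheximide 181 were higher and 484 lower (2421 and 1873, from 1 array at 24 h), with DHCR7 at -3.49 ± 0.42, and under rapamycin 6 and 26 (1084 and 1147), with the stress gene DDIT3 at -2.37 ± 0.28 and CHAC1 at -2.13 ± 0.27. Under geldanamycin 0 were higher and 3 lower (398 and 371), HSPA4L at -1.78 ± 0.36, SLC7A11 at -1.76 ± 0.33 and the co-chaperone gene BAG3. Etoposide had 13 higher, led by GDF15 at 3.00 ± 0.46, and 0 lower (673 and 732), monastrol 1 and 8 (1299 and 1869), and vincristine 1, H2BC15 at 1.86 ± 0.36, and 0 (204 and 365). Mitomycin C, with 531 and 1801 (1673 and 1781), and H-7, with 815 and 1510 (3311 and 2096), again depended on a low-signal array. Aclacinomycin A and blebbistatin had 0 by limma, with 22 and 146 at an unadjusted p under 0.05, and 0 and 720 without the low-signal arrays. With 1 replicate left out in turn the counts were 266 to 5799 for mitomycin C, 453 to 5241 for H-7, 564 to 2933 for trichostatin A, 192 to 1867 for cycloheximide, 111 to 485 for camptothecin, 74 to 215 for doxorubicin, 13 to 101 for rapamycin, 5 to 15 for etoposide, 0 to 72 for monastrol, 0 to 8 for geldanamycin, 0 to 3 for blebbistatin and 0 to 2 for vincristine. At 12 h, where 31 of 94 arrays were low, changed genes numbered as follows, with the range over leaving out 1 replicate in turn and then the count without the low-signal arrays in brackets. Trichostatin A had 1916 (771 to 3760, then 5710), camptothecin 1664 (769 to 3288, then 5066), rapamycin 905 (245 to 1891, then 2406 from 1 array), H-7 605 (116 to 1696, then 4715), cycloheximide 535 (94 to 2004, then 4435), geldanamycin 83 (14 to 699, then 1754), etoposide 27 (7 to 839, then 385 from 1 array), mitomycin C 25 (6 to 115, then 346) and monastrol 4 (0 to 164, then 1063). Doxorubicin had 657 (99 to 3768), blebbistatin 651 (86 to 1631) and aclacinomycin A 10 (2 to 88), all 3 on low-signal arrays alone. Methotrexate had 0 (0 to 0, then 32) and vincristine 0 (0 to 27, then 156) by limma, where 743 and 521 had an unadjusted p under 0.05.

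The higher and the lower concentration of a compound were compared directly at 24 h, with counts without the low-signal arrays in brackets. Between 0.01 and 0.31 uM camptothecin, 78 genes were higher and 521 lower (2683 and 2184) at the higher one, with RABGAP1L at -4.18 ± 0.38, GPHN at -3.91 ± 0.30 and CCL22 at 2.20 ± 0.42. Between 0.03 and 0.101 uM doxorubicin, 42 were higher and 9 lower (1173 and 1787), led by GDF15 at 4.63 ± 0.49 and PODXL at 3.01 ± 0.33. Between 0.264 and 5 uM cycloheximide, 497 were higher and 685 lower (3207 and 2470, from 1 array at 5 uM), with KLF2 at 2.48 ± 0.38 and DNAJB5 at -3.19 ± 0.55. Between 13.8 and 22 uM rapamycin, 8 were higher, led by HSPA6 at 2.41 ± 0.29, and 3 lower (462 and 898). Geldanamycin had 3 higher, CLU at 1.68 ± 0.27, CTLA4 at 1.53 ± 0.31 and GPR155 at 1.51 ± 0.24, trichostatin A 4, led by HHLA2 at 1.48 ± 0.25, and blebbistatin 1, IFIT2 at 2.47 ± 0.33, with 0 lower for each (282 and 369, 733 and 630, and 262 and 285). Mitomycin C had 241 higher and 792 lower (634 and 684), of which 1 in all was left without replicate 2 (4170 without replicate 1, 7647 without replicate 3), and H-7 1690 and 1806, whose lower concentration had low-signal arrays alone (2029 without replicate 2, 8029 without replicate 3). Aclacinomycin A, vincristine and monastrol had 0 by limma, with 5, 1154 and 1174 at an unadjusted p under 0.05. These 3 counts were 0, 89 and 3868 without the low-signal arrays. With 1 replicate left out in turn, 16 to 41 genes passed for doxorubicin, 228 to 563 for camptothecin, 304 to 1275 for cycloheximide, 4 to 18 for rapamycin, 0 to 129 for trichostatin A, 0 to 65 for monastrol, 0 to 4 for geldanamycin and 0 to 1 for blebbistatin. At the lower concentration against DMSO at 24 h, with brackets as for 12 h, etoposide changed 677 genes (173 to 2130, then 3786), camptothecin 217 (98 to 205, then 3853), mitomycin C 206 (101 to 201, then 3727), doxorubicin 203 (84 to 227, then 4291), trichostatin A 89 (48 to 96, then 3329), rapamycin 77 (25 to 816, then 3096) and monastrol 1 (0 to 4, then 256), and H-7 10773 (5393 to 11226) on low-signal arrays alone. Aclacinomycin A had 0 (0 to 0, then 0), vincristine 0 (0 to 561, then 176), blebbistatin 0 (0 to 21, then 964), cycloheximide 0 (0 to 0, then 1639) and geldanamycin 0 (0 to 0, then 0), with 26, 2104, 2072, 223 and 11 at an unadjusted p under 0.05.

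Untreated medium was compared with DMSO to measure the effect of the vehicle (n = 2 and 8). At 6 h 2127 genes were higher and 2524 lower in medium. The chemokine gene CXCL10 was higher by 2.97 ± 0.15, CIITA, the activator of MHC class II genes, by 2.92 ± 0.13, PLAU by 2.36 ± 0.08 and IL6 by 2.08 ± 0.13, and IFIT2 differed by -2.16 ± 0.14 and FOS by -1.80 ± 0.09. Of 31 ribosome biogenesis and MYC-linked genes 20 were higher and 1 lower in medium, at a median of 0.31, and of 30 immediate early genes 3 were higher and 15 lower, at -0.18 (camera, adjusted p = 2.04e-09 and 2.18e-05, and 1.44e-06 and 0.00216 with an estimated correlation). Of 28 lysosome and autophagy genes 2 were higher and 16 lower, at a median of -0.24 (adjusted p = 7.94e-07, and 5.57e-05 with an estimated correlation). At 12 h 64 genes were higher and 12 lower, led by PLAU at 3.39 ± 0.38 and CIITA at 3.13 ± 0.37. At 24 h 98 were higher and 32 lower, with CXCL10 at 2.74 ± 0.20, the phosphatase gene PTPRC at 2.53 ± 0.29, CIITA at 2.50 ± 0.32 and TNFRSF19 at -2.17 ± 0.51. Without the low-signal arrays 1217 were higher and 1416 lower at 12 h, and 1664 and 2021 at 24 h. With 1 replicate left out in turn, 2826 to 4625 genes differed at 6 h, 6 to 195 at 12 h and 35 to 245 at 24 h.

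IFIT2 rose under 9 of 14 compounds, SAT1, which acetylates polyamines, under 8, and NECTIN4, PARP14 and TRIM22 under 7 each. HK2, FAM111B, AFF3, the ubiquitin ligase gene SKP2 and POLR3G, a subunit of RNA polymerase III, fell under 9 each. SAT1 also fell under H-7, and without the low-signal arrays NECTIN4 fell under 3. At least 5 compounds raised 129 genes and lowered 187 (independent lists of these lengths: 0.115 and 0.519). Neither such lists, blind to the shared DMSO arrays, nor 5 simulations of unchanged groups (0, few genes called) can test sharing. Without the low-signal arrays counts were 1931 and 2642 (such lists: 262.8 and 380.2).

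**Figure D4:**
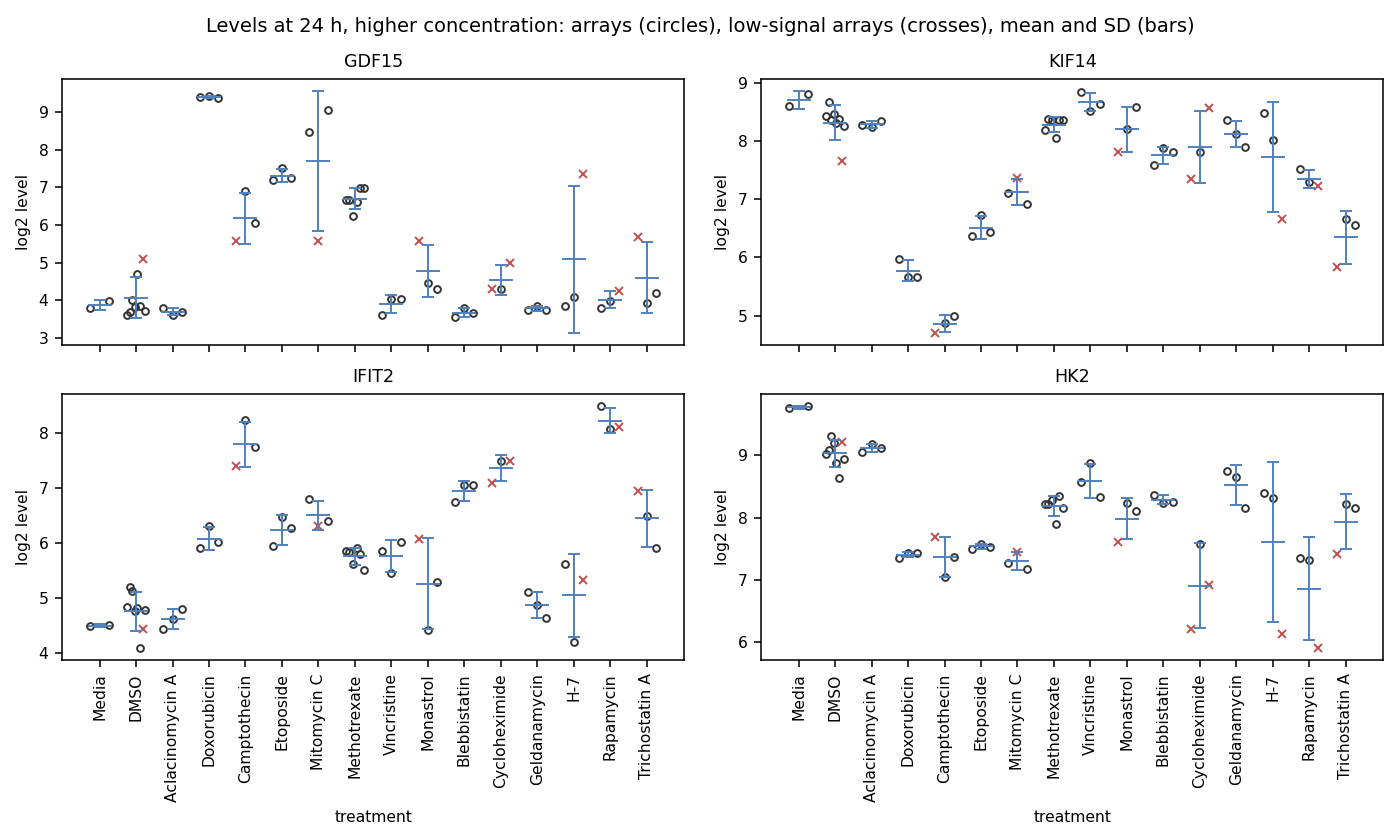
Log2 level of GDF15, KIF14, IFIT2 and HK2 on each array at 24 h (vertical axis) by group (horizontal axis: DMSO, medium and the higher concentration of each compound), with bars for group means and crosses for low-signal arrays. GDF15 averages 4.07 in DMSO and 9.39 under doxorubicin.

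Responses at 24 h were compared with each other across all 18239 genes, which are not independent replicates. The 4 DNA damaging compounds (camptothecin, doxorubicin, etoposide and mitomycin C) had a mean Pearson r of 0.47 over 6 pairs, and doxorubicin and etoposide 0.83. Methotrexate, outside that class, had an r of 0.66 with doxorubicin. The mean was 0.17 for vincristine and monastrol, 0.05 over the 3 pairs of cycloheximide, H-7 and aclacinomycin A, and 0.22 over the 81 other pairs. With DMSO split so that the members of a pair shared no control array, the 4 means were 0.43, 0.09, 0.03 and 0.15. Unchanged groups simulated against the shared DMSO arrays gave a mean r of 0.112 with the spread among DMSO arrays and 0.275 with the spread pooled over all groups, and covariances of 0.00832 and 0.0249. Observed mean covariances were 0.0986, 0.0124, 0.0497 and 0.0346, which exceed the first by 0.0903, 0.00408, 0.0414 and 0.0263 and the second by 0.0737, -0.0125, 0.0248 and 0.00968. The third comes from cycloheximide and H-7, at 0.175, while the other 2 pairs had -0.0122 and -0.014. Without the low-signal arrays the mean r were 0.65, 0.32, 0.09 and 0.24 and those of unchanged groups 0.362 and 0.299, so the first class alone lay above both. The mean covariances were then 0.104, 0.0214, 0.012 and 0.0236, above those of unchanged groups by 0.0981, 0.0155, 0.0061 and 0.0177 with the first spread and 0.0996, 0.017, 0.00757 and 0.0192 with the second. The r of mitomycin C and H-7 went from 0.60 to 0.15 without the low-signal arrays.

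Set tests of all 30 lists at 24 h are given as compounds that raised and that lowered the list, with brackets for the same with an estimated correlation, from all arrays and then without the low-signal arrays. Interferon response genes had 11 and 0 (8 and 0, then 9 and 0), p53 targets 7 and 0 (5 and 0, then 10 and 0), DNA replication genes 1 and 12 (0 and 3, then 1 and 10), mitosis genes 1 and 9 (0 and 4, then 1 and 8), DNA repair genes 1 and 10 (0 and 1, then 2 and 10), tubulin genes 1 and 4 (0 and 2, then 0 and 4), histone genes 6 and 1 (1 and 0, then 6 and 1), immediate early genes 8 and 1 (1 and 0, then 10 and 1) and NRF2 and metal response genes 2 and 1 (1 and 1, then 1 and 0). For the lists that follow, all arrays gave 0 calls with an estimated correlation, and brackets hold those without the low-signal arrays: ribosome biogenesis and MYC-linked genes 0 and 12 (0 and 9), folate and nucleotide synthesis genes 0 and 12 (0 and 11), glycolysis and hypoxia genes 1 and 11 (1 and 10), cholesterol and fatty acid synthesis genes 1 and 10 (0 and 10), endoplasmic reticulum chaperone genes 1 and 6 (0 and 3), oxidative phosphorylation genes 1 and 3 (1 and 0), heat shock genes 3 and 3 (3 and 1), ATF4 and amino acid response genes 3 and 2 (3 and 1), actin and myosin cytoskeleton genes 1 and 2 (1 and 1), aryl hydrocarbon receptor targets 1 and 2 (0 and 0), ribosomal protein genes 2 and 1 (0 and 0), NF-kappaB targets 5 and 1 (4 and 1), lysosome and autophagy genes 8 and 1 (7 and 0) and apoptosis regulators 3 and 0 (3 and 0). B cell identity genes and plasma cell genes were called under 0 compounds, with medians from -0.10 to 0.15 and from -0.14 to 0.03 (up under 2 and 0 without the low-signal arrays). Of the markers of other cell types, those of T cells and NK cells were called under 0. Myeloid markers were called up under 2 (mitomycin C at 0.55 and monastrol at 0.11) and down under vincristine (-0.16), erythroid and platelet markers up under mitomycin C (0.57), and fibroblast and epithelial markers up under H-7 (0.32), and 0 of these calls held with an estimated correlation, or without the low-signal arrays.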

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

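The tests of array material, degraded RNA, cell loss, media arrays with bioB and aclacinomycin A without low-signal arrays were chosen after seeing the results. The other tests here were not. The 48 low-signal arrays of 12 and 24 h, 31 and 17 of them, lay in 32 groups and included 5 DMSO and 0 medium arrays. At 24 h their median bioB level was 12.43 against 8.80 on the other arrays, a difference of 3.63 (SD of the others 0.85), and at 12 h 13.02 against 10.54, a difference of 2.48 (SD 1.24). A control added in fixed amount takes a larger share where there is less sample, so less material on these arrays may explain them. Degraded RNA cannot be told apart from it: 38 of the 48 had a GAPDH 3' to 5' difference no higher than the highest of the other arrays, but their medians were higher by 0.13 at 12 h and 0.34 at 24 h (SD of the others 0.08 and 0.12). Cell loss under a drug stays open: 27 of 32 groups held an unaffected replicate, but 5 drug groups none.

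Medium and DMSO differed in 4651 genes at 6 h, more than under 9 of the 14 compounds at their higher concentrations. Less material on the media arrays is argued against, since 4958 genes differed with bioB as a covariate. A response of the cells to the vehicle may explain the difference. The fold changes at 6 and 24 h had an r of 0.51 across 18239 genes without the low-signal arrays (0.49 with all), and those at 6 and 12 h 0.67 (0.56). Of the 4651 genes, 91.55% had the same sign at 12 h and 79.51% at 24 h. The place of the wells on a plate cannot be told apart from this, because 0 media arrays carry a well in their labels.

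Aclacinomycin A changed 0 genes at 24 h. Spread added by low-signal arrays is argued against as the reason, since the count without them was 0 while doxorubicin reached 6514. No effect of the drug at this concentration at any time stays open, because 6 of 100 splits at 6 h gave as many genes as the real 141, with 820 as the highest other. A change below the limit of the test at 24 h may be part of it and cannot be told apart: 73.76% of the 141 genes kept their direction at 24 h, and r between the 6 and 24 h changes was 0.13.

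Regrouping the arrays showed where chance can be excluded. At 24 h 1 of 100 splits, the real one, gave as many genes for the higher concentrations of doxorubicin (1107, highest other 30), camptothecin (1497, 119), etoposide (265, 4), methotrexate (865, 287), vincristine (8, 0), blebbistatin (9, 0), cycloheximide (2460, 1863), geldanamycin (4, 0) and rapamycin (455, 100), and for the lower ones of doxorubicin (203, 1), camptothecin (217, 2), mitomycin C (206, 2), H-7 (10773, 7597) and trichostatin A (89, 0). For monastrol (220, 324) and trichostatin A (912, 1007) it was 2 splits, for etoposide (677, 796) and rapamycin (77, 252) at the lower concentration 3, and for monastrol at the lower concentration 4 (1, 5). Chance cannot be excluded for mitomycin C at 24 h, with 6 splits (4711, 7022), and for H-7, with 8 (3770, 6836). The real counts fell to 552 without replicate 2 and 51 without replicate 3, their low-signal arrays. Comparisons with 0 genes are matched by all 100 splits, among them aclacinomycin A at both concentrations (highest other 0) and the lower concentrations of vincristine (983), blebbistatin (84), cycloheximide (0) and geldanamycin (0).

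At 6 h 1 of 100 splits was as large for camptothecin (8550, 5415), H-7 (9126, 5783), trichostatin A (8160, 5091), cycloheximide (6091, 2698), rapamycin (4849, 1718), geldanamycin (3006, 615), monastrol (1385, 458), doxorubicin (1303, 439), etoposide (834, 446), mitomycin C (542, 387) and blebbistatin (472, 252). The same held at the lower concentrations of camptothecin (666, 175), etoposide (1156, 646), vincristine (476, 154), cycloheximide (1781, 393), H-7 (6101, 2977), rapamycin (3254, 1034) and trichostatin A (8088, 4996). It was 2 splits for monastrol (268, 397), blebbistatin (480, 2280) and geldanamycin (15, 19) and 3 for mitomycin C (171, 434), all lower, 3 for methotrexate (320, 1039) and 4 for doxorubicin at the lower concentration (100, 625). Chance cannot be excluded for vincristine at 6 h, with 7 splits (173, 515), and aclacinomycin A, with 6 (141, 820). Its lower concentration had 0 genes, which all 100 splits match by construction (highest other 141).

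At 12 h 1 split of 100 was as large for camptothecin (1664, 783) and trichostatin A at both concentrations (1916, 381 and 1422, 465), 2 for cycloheximide (535, 565) and H-7 (605, 649), 3 for rapamycin (905, 1153) and for camptothecin at the lower concentration (32, 560), and 4 for doxorubicin (657, 1968), blebbistatin (651, 2880), geldanamycin (83, 570) and H-7 at the lower concentration (25, 971). Chance cannot be excluded for etoposide with 8 splits (27, 1353), monastrol 9 (4, 328), aclacinomycin A 12 (10, 408) and mitomycin C 13 (25, 2845), nor at lower concentrations for rapamycin 5 (28, 565), blebbistatin 6 (72, 1687), doxorubicin 7 (9, 404), etoposide 10 (45, 1237), vincristine 12 (2, 580), geldanamycin 25 (5113, 11053) and cycloheximide 30 (1, 1194). With 0 genes, methotrexate (7), vincristine (308), and at lower concentrations aclacinomycin A (569), mitomycin C (627) and monastrol (580) are matched by 100.

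For medium against DMSO 1 of 45 splits was as large at 6 h (4651, highest other 501) and at 24 h (130, 1), and 4 of 45 at 12 h (76, 849), where chance cannot be excluded. Contrasts of 3 with 3 arrays have 10 splits, too few for a share under 0.05. Real and highest other counts between doxorubicin and aclacinomycin A were 693 and 13, 110 and 70, and 580 and 0 at 6, 12 and 24 h, and 39, 3 and 75 against 0 each at the lower pair. Between concentrations at 24 h they were 51 and 0 for doxorubicin, 599 and 0 for camptothecin, 1033 and 1373 for mitomycin C (2 splits), 1182 and 0 for cycloheximide, 3496 and 10917 for H-7 (4 splits), 11 and 7 for rapamycin, 4 and 1 for trichostatin A, 3 and 0 for geldanamycin, 1 and 0 for blebbistatin, 0 and 22 for monastrol, and 0 and 0 for aclacinomycin A, etoposide and vincristine.

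Responses at 24 and 6 h differed in 205 genes for doxorubicin (highest other 10 in 100 splits), 351 for camptothecin (14), 13 for etoposide (1), 457 for methotrexate (83), 9 for monastrol (2), 665 for cycloheximide (355), 3 for geldanamycin (0), 2325 for H-7 (2093), 32 for rapamycin (2) and 1790 for trichostatin A (399), with 1 split each as large. For vincristine 2 splits gave 1 gene or more (1, 1), and for mitomycin C 7 splits (2332, 3793), so chance cannot be excluded for the latter. Aclacinomycin A and blebbistatin had 0 genes here in the real and every other split. Of 4040 probe sets without a single gene name, doxorubicin at 24 h changed 144, with 93 up and 51 down.

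Among 204 sets of values of a group with at least 6 arrays, 39 held an array far from the rest, where chance gives about 1 in 20 if the sets are independent, which these are not. In DMSO at 6 h replicate 2 had an ACTB difference of 0.31 and replicate 8 a folate list mean of 9.86. In DMSO at 12 h replicate 1 had means of 7.71 for histone and 9.24 for glycolysis genes, and replicate 8 one of 5.17 for erythroid markers. In DMSO at 24 h replicate 7, a low-signal array, had an upper quartile of 7.98 and means of 8.7 for p53, 9.68 for mitosis, 9.62 for replication, 10.35 for endoplasmic reticulum and 8.94 for immediate early genes, and replicate 5 one of 7.74 for plasma cell genes. Methotrexate array A03 at 6 h had GAPDH and ACTB differences of 0.5 and 0.9 and means of 8.81 for p53, 6.67 for interferon, 9.65 for tubulin, 6.54 for T cell and 4.76 for erythroid genes. Methotrexate array A02 at 12 h, a low-signal array, had an upper quartile of 7.61 and means of 8.49 for p53, 8.75 for mitosis, 9.35 for replication, 7.57 for repair, 10.32 for heat shock, 8.6 for ATF4, 9.05 for cholesterol, 8.88 for NF-kappaB, 9.68 for ribosome biogenesis, 8.63 for immediate early, 6.13 for interferon, 8.34 for apoptosis, 10.25 for actin, 9.26 for glycolysis and 9.15 for lysosome genes. Array A03 at 12 h had a GAPDH difference of -0.24 and a ribosomal protein mean of 13.33. At 24 h array A04 had a myeloid mean of 4.31 and methotrexate replicate 3 an erythroid mean of 4.73.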

How the results depend on the processing

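The low-signal arrays, the bioB covariate, the array weights and the second simulation of similarity were chosen after the data were seen; the other settings were not. Counts over all comparisons and times moved often: of 110 counts 70 moved by over 1.5 times without the low-signal arrays, and of 117 counts 94 moved with array weights, 75 with only the groups compared, 51 with the replicate block, 49 with quantile normalization again, 46 with bioB, 42 with the mean of all probe sets and 14 without the lowest genes. Of up to 448 values of named genes, at most 3 were reversed under any of these settings and at most 80, with the replicate block, were no longer called. Leaving out 1 replicate moved 293 of 1147 counts. Replicate numbers were not seen to pair the arrays. At 6, 12 and 24 h 0 of 14 comparisons had all same-number correlations over 0.1, and the median r was -0.01, 0 and -0.03. Of 42 drug arrays, 5, 6 and 9 correlated best with their own number among 8 DMSO arrays. Chance gives about 1 in 8, so some pairing at 24 h is not excluded. DMSO replicates 4 to 8 share their number with no group of 3 arrays. H-7 at its lower concentration at 24 h, and at 12 h blebbistatin at both, doxorubicin and aclacinomycin A at their higher concentration, have no value without the low-signal arrays. The cause of the moves was not tested.

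Some values, or the directions of their tests, turned. For mitomycin C, repair went from -0.29 to 0.16, 0.13 and 0.16 (without low-signal arrays, with weights, without replicate 2), actin from -0.33 to 0 with weights and without replicate 2, myeloid markers from 0.55 to -0.09 and -0.10 without low-signal arrays and without replicate 2, erythroid markers from 0.57 to -0.04 without replicate 2, FANCG from -1.01 to 0.03, 0.04 and 0.03, and the concentration effect on ITGA2 from 1.70 to -0.13, -0.10 and -0.08, in the order of repair. Over all replicates left out, the values farthest the other way were -0.66 for repair, -0.50 for actin, 0.73 for myeloid and 0.84 for erythroid markers, -1.57 for FANCG and 2.64 for ITGA2. For H-7, oxidative phosphorylation (-0.36) gave 0.10, 0.09 and 0.11 without low-signal arrays, with weights and without replicate 3, and its test turned at -0.36 without the lowest genes; ribosome biogenesis went from -0.55 to -0.01 without replicate 3, and the actin test turned at -0.03 and -0.02 (main -0.46) without low-signal arrays and without replicate 3. Without replicate 1 these 3 stood at -0.61, -0.85 and -0.74. With bioB, cholesterol went from 0.04 to -0.07 for aclacinomycin A, ribosome biogenesis from -0.28 to 0.21 and myeloid markers from 0.11 to -0.08 for monastrol, and for cycloheximide immediate early genes from -0.12 to 0.39, ribosome biogenesis from -0.23 to 0.27 and repair from -0.29 to 0.15. Under cycloheximide TNFAIP3 went from 0.42 to 0 and EGR3 from -1.04 to 0.15 with the mean of all probe sets, and EGR1 from -0.95 to 0.05 without low-signal arrays. Genes shared by at least 5 compounds numbered 129 up and 187 down. The rises were 219 with quantile normalization again and 219 with bioB, and rises and falls were 59 and 54 with the replicate block, 1931 and 2642 without low-signal arrays, 1770 and 2327 with weights and 455 and 1086 with only the groups compared. Mean similarity moved to 0.65 for DNA damaging and 0.09 for translation or transcription compounds without low-signal arrays, and for pairs of no common class (0.22) to 0.15 with split DMSO, 0.23 without the lowest genes, 0.21 with quantile normalization again and 0.24 without low-signal arrays. In the same 4 settings vincristine and monastrol (0.17) had 0.09, 0.31, 0.24 and 0.32. A mean counts as moved beyond its SD over left-out replicates, which was 0.162 for this pair, the largest, and 0.005 for pairs of no common class.

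Array weights gave, at 6 h, aclacinomycin A 235, doxorubicin 2427, etoposide 1320, mitomycin C 848, methotrexate 13, vincristine 18 and blebbistatin 1882. The counts at 24 h were doxorubicin 7475, camptothecin 7090, etoposide 5539, methotrexate 7119, vincristine 1392, monastrol 2308, blebbistatin 2924, geldanamycin 837, H-7 1485, rapamycin 5584 and trichostatin A 3927. The counts between concentrations were doxorubicin 3921, camptothecin 6265, etoposide 197, vincristine 103, monastrol 1063, blebbistatin 1153, cycloheximide 2772, geldanamycin 748, H-7 6070, rapamycin 1360 and trichostatin A 290. The counts between 24 and 6 h were aclacinomycin A 1, doxorubicin 5410, camptothecin 5861, etoposide 2617, mitomycin C 4104, methotrexate 5791, vincristine 549, monastrol 1876, blebbistatin 1489, cycloheximide 2442, geldanamycin 1123, H-7 4117, rapamycin 3544 and trichostatin A 6546. Medium against DMSO gave 2607 at 12 h and 4880 at 24 h. The anthracycline pair gave 1424 at 6 h, 210 at 12 h and 7158 at 24 h.

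The mean of all probe sets gave, at 6 h, methotrexate 540. At 24 h it gave etoposide 457, methotrexate 1395 and vincristine 15. Between concentrations it gave doxorubicin 79, mitomycin C 58, monastrol 2, cycloheximide 2124 and trichostatin A 1. Between 24 and 6 h it gave doxorubicin 394, camptothecin 686, etoposide 20, methotrexate 922, vincristine 5, monastrol 36, cycloheximide 1380, geldanamycin 9 and rapamycin 113. Between medium and DMSO it gave 235 at 12 h and 225 at 24 h. Between the anthracyclines it gave 888 at 24 h.

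Using only the groups compared gave, at 6 h, aclacinomycin A 0, methotrexate 0 and vincristine 14. The counts at 24 h were doxorubicin 4832, camptothecin 4585, etoposide 2573, mitomycin C 306, methotrexate 5298, vincristine 326, monastrol 2257, blebbistatin 798, cycloheximide 5465, geldanamycin 130, H-7 19, rapamycin 2827 and trichostatin A 2545. The counts between concentrations were doxorubicin 3455, camptothecin 3757, mitomycin C 0, blebbistatin 0, geldanamycin 389, H-7 0, rapamycin 0 and trichostatin A 0. The counts between 24 and 6 h were doxorubicin 3266, camptothecin 3828, etoposide 1012, mitomycin C 553, methotrexate 4348, vincristine 265, monastrol 1889, blebbistatin 423, cycloheximide 4610, geldanamycin 426, H-7 1479, rapamycin 1670 and trichostatin A 5507. Medium against DMSO gave 409 at 12 h and 1409 at 24 h. The anthracycline pair gave 312 at 6 h and 7127 at 24 h.

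Quantile normalization again gave, at 6 h, aclacinomycin A 88. At 24 h it gave etoposide 447, vincristine 38, blebbistatin 46, geldanamycin 7 and rapamycin 756. Between concentrations it gave doxorubicin 82, mitomycin C 2009, monastrol 3, blebbistatin 2, geldanamycin 6, H-7 5521, rapamycin 122 and trichostatin A 9. Between 24 and 6 h it gave doxorubicin 315, vincristine 9, monastrol 5, blebbistatin 4, geldanamycin 7, H-7 3649 and rapamycin 85. Between medium and DMSO it gave 160 at 12 h and 211 at 24 h. Between the anthracyclines it gave 246 at 12 h.

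The replicate number as a block gave, at 6 h, aclacinomycin A 4, doxorubicin 814, methotrexate 2 and blebbistatin 114. The counts at 24 h were doxorubicin 588, camptothecin 944, etoposide 112, mitomycin C 2430, methotrexate 311, vincristine 2, monastrol 69, blebbistatin 1, cycloheximide 1178, geldanamycin 1, H-7 968, rapamycin 197 and trichostatin A 402. Mitomycin C between concentrations gave 400. Medium against DMSO gave 74 at 24 h.

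The bioB level as a covariate gave, at 6 h, aclacinomycin A 35 and vincristine 100. At 24 h it gave doxorubicin 1677, etoposide 524, mitomycin C 2314, methotrexate 1302, vincristine 26, monastrol 112, blebbistatin 24, H-7 525 and rapamycin 744. Between concentrations it gave doxorubicin 90, mitomycin C 4, monastrol 1 and rapamycin 57. Between 24 and 6 h it gave doxorubicin 370, camptothecin 676, mitomycin C 1129, methotrexate 700, vincristine 5, monastrol 4, blebbistatin 4, geldanamycin 5 and rapamycin 53. Between medium and DMSO it gave 128 at 12 h and 222 at 24 h. Between the anthracyclines it gave 288 at 12 h and 917 at 24 h.

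Leaving out the low-signal arrays gave, at 24 h, doxorubicin 6514, camptothecin 6206, etoposide 4555, methotrexate 6498, vincristine 1683, monastrol 5986, blebbistatin 2583, cycloheximide 6347, geldanamycin 949, rapamycin 5054 and trichostatin A 5696. The counts between concentrations were doxorubicin 2960, camptothecin 4867, etoposide 37, vincristine 89, monastrol 3868, blebbistatin 547, cycloheximide 5677, geldanamycin 651, rapamycin 1360 and trichostatin A 1363. The counts between 24 and 6 h were doxorubicin 3709, camptothecin 4344, etoposide 1405, methotrexate 4960, vincristine 569, monastrol 3168, blebbistatin 720, cycloheximide 4294, geldanamycin 769, H-7 5407, rapamycin 2231 and trichostatin A 6598. Medium against DMSO gave 2633 at 12 h and 3685 at 24 h. The anthracycline pair gave 5623 at 24 h.

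Leaving out the lowest genes gave, at 6 h, aclacinomycin A 88 and methotrexate 549. Between concentrations it gave monastrol 2, H-7 2278 and trichostatin A 0.

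Leaving out 1 replicate at a time, DMSO included, gave ranges where a count moved. At 6 h these were aclacinomycin A 0 to 432, doxorubicin 712 to 1401, etoposide 453 to 844, mitomycin C 258 to 555, methotrexate 6 to 1108 (714 without array A05/A06), vincristine 17 to 627, monastrol 572 to 1433, blebbistatin 130 to 716 and geldanamycin 1913 to 2946. Between medium and DMSO these were 2826 to 4625 at 6 h, 6 to 195 at 12 h and 35 to 245 at 24 h. Between the anthracyclines these were 312 to 467 at 6 h, 20 to 1285 at 12 h and 251 to 523 at 24 h. At 24 h these were doxorubicin 630 to 1149, camptothecin 939 to 1676, etoposide 124 to 270, mitomycin C 552 to 9722, vincristine 0 to 9, monastrol 9 to 909, blebbistatin 1 to 8, cycloheximide 1354 to 3330, geldanamycin 0 to 4, H-7 51 to 7480 and trichostatin A 197 to 2631. Between concentrations these were doxorubicin 16 to 41, camptothecin 228 to 563, mitomycin C 1 to 7647, monastrol 0 to 65, blebbistatin 0 to 1, cycloheximide 304 to 1275, geldanamycin 0 to 4, H-7 2029 to 8029, rapamycin 4 to 18 and trichostatin A 0 to 129. Between 24 and 6 h these were doxorubicin 74 to 215, camptothecin 111 to 485, etoposide 5 to 15, mitomycin C 266 to 5799, vincristine 0 to 2, monastrol 0 to 72, blebbistatin 0 to 3, cycloheximide 192 to 1867, geldanamycin 0 to 8, H-7 453 to 5241, rapamycin 13 to 101 and trichostatin A 564 to 2933.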
